A study of Mus musculus with 12 samples.

How the data were processed

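Messenger RNA of sorted mouse bone marrow cells was measured in 12 libraries, 3 from each of 4 genotypes. Per the labels' protocols, the cells were lineage-negative, Sca-1-positive and c-Kit-positive (LSK), the gate that holds haematopoietic stem cells and multipotent progenitors. RNA was taken with a micro-column kit and amplified to full-length cDNA with a SMART-Seq low-input kit. Such a kit starts from oligo-dT priming and does not mark strand, so reads of a gene and of an antisense partner could not be told apart. The libraries were sequenced on a HiSeq 4000.

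The authors deposited a table of 37187 genes by 12 libraries whose values are a normalised signal, that is whole reads per gene divided by a size factor per library. The submitters' processing notes name bcl2fastq, STAR, featureCounts and DESeq2 and the builds mm10 and GRCm38. Versions, settings, gene annotation and the strand setting of the counting were not given in the sources used here. Dividing each library's deposited values by its smallest value above 0 gave whole numbers for 100% of values in every library (tolerance 1e-06), so the reads behind the deposited signal were recovered. They numbered 22169673 to 53921402 per library, and each read was worth 0.518 to 1.79 signal units. A gene at 0 in all 3 libraries of a group was set to a floor of 3 reads per library, and a fold against such a group is given as a lower bound. Floors cover counting error only, since reads copied by PCR are not independent molecules.

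Because the values are normalised and not raw counts, the main test was limma 3.58.1 (R 4.3.3) with trend and robust moderation on log2(value + 1). This followed the design fixed before the data were examined. The fit held all 12 libraries as 4 genotype groups without covariates, so the groups shared 1 estimate of the spread. Genes with a value of at least 10 in at least 3 libraries were tested, 14045 in all. Comparisons were Tet2 KO, Traf6 KO and dKO each against WT, dKO against each single knockout, and the interaction, (dKO minus Tet2 KO) minus (Traf6 KO minus WT). Adjusted p-values are Benjamini-Hochberg values within a comparison and 0.05 was the threshold. Fold changes are on the log2(value + 1) scale, which understates changes of genes with few reads. The labels do not say that the 3 libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical.

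The 26 gene lists were fixed before the data were examined and hold 1010 distinct genes found in the table. They cover MYC targets, ribosome biogenesis, cytosolic ribosomal proteins, oxidative phosphorylation, glycolysis, G1/S phase, G2/M phase, NF-kB targets, type I interferon response, Toll-like receptor and TRAF6 signalling, p53 targets, immediate early and dissociation stress genes, unfolded protein and integrated stress response, cholesterol and fatty acid synthesis, and DNA methylation and TET partners. Cell programmes covered were haematopoietic stem cell, neutrophil and monocyte progenitor, mature neutrophil, macrophage and dendritic cell, megakaryocyte, erythroid, lymphoid progenitor, mature B, T and NK cell, mast cell and basophil, stromal and endothelial, and HOXA cluster genes. Lists were tested with camera in limma, which compares a list with all other genes, at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the lists of a comparison.

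Genes named in the text followed a rule fixed before the data were examined. Per comparison it took the 10 largest rises and the 10 largest falls among genes past the threshold whose groups did not overlap (a condition not used for the interaction), with a mean of at least 50 in the higher group, leaving out predicted genes and immunoglobulin or T cell receptor segments. It added Tet2, Traf6 and Myc, up to 4 members with the smallest p per list and the 3 most abundant members of each list of another cell type. Sex-linked genes outside the rule, and the genes shared by both single knockouts, were chosen after their values were seen. Gene positions and the length and GC content of the longest transcript came from GENCODE M21 on GRCm38, in which 30465 of the 37187 genes were found, 28387 by symbol and 2078 through a synonym. A length was at hand for 13668 of the 14045 tested genes (97.3%).

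Alternatives fixed beforehand were a pseudocount of 5, no filter on low values, equal library totals, a replicate block, each library left out in turn, the 2 compared groups alone, and on the recovered reads edgeR 4.0.16 (quasi-likelihood test, TMM scaling) and DESeq2 1.42.0. On those reads edgeR called 43, 28, 6539, 4881, 5171 and 27 genes in the 6 comparisons in the order above, and DESeq2 called 300, 167, 7478, 6122, 6392 and 259. After the data were seen, further alternatives were added. In the first, a loess trend of the log2 values on transcript length and GC content was taken off in each library, also combined with the replicate block, with an estimated correlation, or without dKO replicate 3. In the other, limma weighted the spread by group (weights 2.27 for WT, 1.21 for Tet2 KO, 0.99 for Traf6 KO and 0.37 for dKO). Each pair of libraries within a group differed by more than counting noise (chi-square per degree of freedom 19.6 to 605), and all were counted as separate libraries.

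The code was tested on simulated reads drawn from each gene's mean over all libraries, its fitted dispersion and the real depths. For Tet2 KO against WT, 6% of 100 genes changed by 1 on the log2 scale and 67% of 100 changed by 2 were called, with 3 false calls among 76, over 13721 tested genes. For dKO against Tet2 KO the shares were 9% and 71%, with 3 false calls among 83, over 13717 tested genes. A simulated length trend between those groups gave 1453 calls before and 0 after the trend was taken off. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.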

Results

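The series set gene expression of LSK cells, the stem and progenitor compartment of mouse bone marrow, side by side in wild-type mice (WT), mice lacking Tet2 (Tet2 KO), mice lacking Traf6 (Traf6 KO) and mice lacking both genes (dKO). Tet2 encodes an enzyme that oxidises 5-methylcytosine in DNA, and Traf6 encodes a ubiquitin ligase that relays Toll-like and interleukin-1 receptor signals to NF-kB. The title ties TRAF6 to the activity of MYC, a transcription factor that drives growth genes, in acute myeloid leukaemia. Each genotype had 3 libraries. Recovered reads in replicates 1, 2 and 3 were 36807003, 23599252 and 28762525 in WT and 24231256, 28159971 and 53921402 in Tet2 KO. They were 30449291, 24123131 and 32307868 in Traf6 KO and 30555015, 22169673 and 22366851 in dKO.

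The targeted genes were read first, as a check of the labels. Traf6 (chromosome 2, 101678429 to 101701669, GRCm38) stood at 2632 ± 604 (SD, n = 3) in WT, 2112 ± 896 in Tet2 KO, 1299 ± 1028 in Traf6 KO and 1026 ± 262 in dKO, as mean normalised signal ± SD. Within the Traf6 KO group the values were 854 and 568 in replicates 2 and 3, but 2474 in the library labelled Traf6 KO replicate 1, inside the WT range of 1935 to 3006. Tet2 (chromosome 3, 133463679 to 133545139) stood at 682 ± 138 in WT, 519 ± 136 in Tet2 KO, 496 ± 201 in Traf6 KO and 261 ± 64.3 in dKO. Within the Tet2 KO group the Tet2 values were 403 and 486 in replicates 2 and 3 and 668 in the library labelled Tet2 KO replicate 1, inside the WT range of 525 to 783. Neither gene passed the test in its own single knockout: Tet2 in Tet2 KO had log2 change -0.41 ± 0.35 (SE), adjusted p = 0.969, and Traf6 in Traf6 KO had log2 change -1.28 ± 0.46 (SE), adjusted p = 0.497, or -1.89 with adjusted p = 0.0724, without the library labelled Traf6 KO replicate 1. Tet2 in Tet2 KO had -0.60 without the library labelled Tet2 KO replicate 1 and -0.24 without Tet2 KO replicate 2, but 0.19 with the length and GC trend removed (adjusted p = 0.958), and Traf6 in Traf6 KO had -0.83 without Traf6 KO replicate 3. In dKO against WT both fell, Tet2 with log2 change -1.39 ± 0.35 (SE), adjusted p = 0.00659, and Traf6 with log2 change -1.36 ± 0.46 (SE), adjusted p = 0.0278. Both calls ended once the length trend described below was removed (0.31 and -0.18). The Traf6 call also ended without WT replicates 2 and 3 (-1.25 and -1.26) and without dKO replicates 1 and 3 (-1.19 and -1.33). The labels do not say which exons were deleted, and reads from remaining exons stay in a gene's total, so these values check the genotypes only in part. Myc (chromosome 15, 61985391 to 61990374) stood at 19394 ± 534 in WT, 21917 ± 2783 in Tet2 KO, 16758 ± 4915 in Traf6 KO and 25425 ± 5056 in dKO, and passed the test in none of the 6 comparisons, with adjusted p = 0.0528 as the smallest, in dKO against Traf6 KO. In that comparison it passed without Traf6 KO replicate 3 (0.82, adjusted p = 0.0457) or dKO replicate 3 (0.80, adjusted p = 0.0261) and with DESeq2 (0.62, adjusted p = 0.0371), and had 0.38 without the library labelled Traf6 KO replicate 1.

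**Figure D1:**
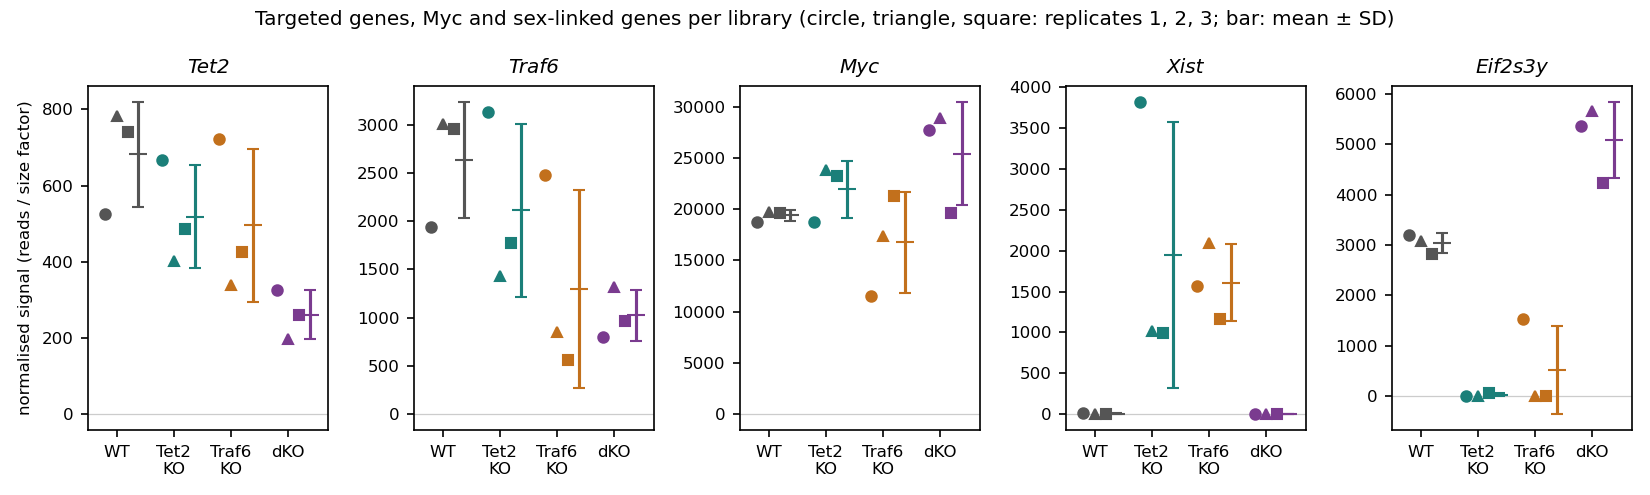
Normalised signal (reads divided by size factor, linear axis) of Tet2, Traf6, Myc, Xist and Eif2s3y in each of the 12 libraries, grouped by genotype. Points are libraries, and bars give the mean ± SD of 3. Traf6 in the library labelled Traf6 KO replicate 1 reached 2474, and the same library held both Xist (1574) and Eif2s3y (1524).

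Sex-linked genes split the libraries in another way than genotype. Xist, the RNA that coats the inactive X chromosome (chromosome X, 103460366 to 103483254), stood between 990.3 and 3826 in the Tet2 KO and Traf6 KO libraries and at 17 or less in WT and dKO. The Y-linked gene Eif2s3y stood between 2812 and 5668 in WT and dKO, at 55.4 or less in Tet2 KO and at 2.3 and 0.9 in Traf6 KO replicates 2 and 3, but at 1524 in the library labelled Traf6 KO replicate 1. Ddx3y, Kdm5d and Uty, also on the Y chromosome, stood at 2815, 571 and 863 in that library. All comparisons except dKO against WT therefore also set libraries with Y-linked reads against libraries without them.

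The dKO libraries also differed from the rest by transcript length. Relative to the WT mean, genes with a longest transcript of up to 1000 nucleotides had median log2 changes of 0.78, 1.20 and 2.84 in dKO replicates 1, 2 and 3, while genes over 4000 nucleotides had -0.81, -1.42 and -1.41. Across genes, which are not independent replicates, the rank correlation with length was -0.52, -0.59 and -0.60 in those libraries, and between -0.40 and 0.29 in the other 9. In dKO replicate 3 the normalised total was 39973892, against 25557760 to 28916082 elsewhere, and its 10 most abundant genes took 5.74% of the signal, against 2.55 to 3.67%. Gene lists past the threshold in dKO comparisons are given below as deposited and with the length and GC trend removed. With that trend removed and the correlation estimated, megakaryocyte genes in Tet2 KO were the list past the threshold in any comparison (adjusted p = 0.00839).

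**Figure D2:**
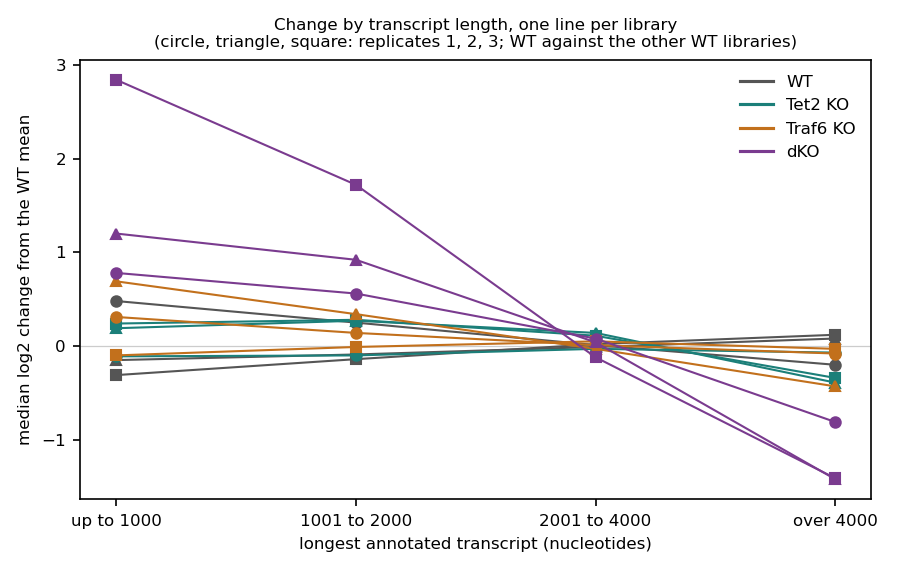
Median log2 change from the WT mean (vertical axis) by class of longest annotated transcript in nucleotides (horizontal axis), with 1 line per library coloured by genotype and each WT library set against the other WT libraries. The 3 dKO libraries fall from 0.78, 1.20 and 2.84 for the shortest transcripts to -0.81, -1.42 and -1.41 for the longest.

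The first comparison asked what Tet2 loss did to LSK cells, and its directions include the library labelled Tet2 KO replicate 1, where Tet2 stood at the WT level. In Tet2 KO, genes of the megakaryocyte programme were lower than in WT. Vwf, which encodes von Willebrand factor of platelets and endothelium and also marks platelet-biased stem cells, fell from 1759 ± 491 to 177 ± 84.4 (SD, n = 3, log2 change -3.40 ± 0.50 (SE), adjusted p = 0.00593). Sdpr fell by 1.75 on the log2 scale (adjusted p = 0.033), and Thbs1, which encodes the platelet protein thrombospondin 1, stood at 129.5 ± 5.5 in WT and at 0 in all 3 Tet2 KO libraries, at least 51-fold lower (adjusted p = 0.0429). Of 26 megakaryocyte genes tested, 0 rose, 3 fell and 23 passed neither way (0 and 8 adjusted over the list alone), with median log2 change -0.68, camera adjusted p = 1.71e-09. This was the list of the comparison whose call held with an estimated correlation (adjusted p = 0.00752). Haematopoietic stem cell genes went the same way, and 2 of 48 fell (5 adjusted over the list alone): Vwf and Slamf1, which encodes the stem cell surface marker CD150 (-1.73, adjusted p = 0.0257). That list had median log2 change -0.41, camera adjusted p = 1.69e-05, adjusted p = 0.371 with an estimated correlation.

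Programmes of committed myeloid and erythroid progenitors were higher in Tet2 KO as lists. The 31 erythroid genes had median log2 change 0.90, camera adjusted p = 9.22e-10, adjusted p = 0.371 with an estimated correlation, and no member passed the threshold over all genes. Adjusted over the list alone 8 were higher, among them Rhd, a blood group antigen gene (3.25, adjusted p = 0.0592), and Car1, a red cell carbonic anhydrase (3.13, adjusted p = 0.0838), whose Tet2 KO values ran from 5662 to 54843. Neutrophil and monocyte progenitor genes had median log2 change 0.58, camera adjusted p = 1.71e-09, adjusted p = 0.408 with an estimated correlation, and 2 of 39 were higher when adjusted over the list alone: Ly6c2 (3.40, adjusted p = 0.0592) and Elane, the neutrophil elastase gene (3.60, adjusted p = 0.0952). Lists of other cell types moved both ways, and they may hold genes that LSK cells express themselves, such as Vwf. Mature neutrophil genes had median log2 change -1.17, camera adjusted p = 0.017, adjusted p = 0.602 with an estimated correlation (S100a9 375 in WT and 85.8 in Tet2 KO). Macrophage and dendritic cell genes had median log2 change -0.70, camera adjusted p = 0.0269, adjusted p = 0.749 with an estimated correlation. Stromal and endothelial genes had median log2 change -1.43, camera adjusted p = 0.0121, adjusted p = 0.152 with an estimated correlation, with Vwf as the called member. With genes at 0 set to their bound that last median was -1.27, and with the length and GC trend removed it was -0.91. Lymphoid progenitor genes had median log2 change 0.66, camera adjusted p = 0.016, adjusted p = 0.693 with an estimated correlation. Mature B, T and NK cell genes had median log2 change 1.28, camera adjusted p = 0.017, adjusted p = 0.602 with an estimated correlation, with Igkc at 12259 in Tet2 KO replicate 2, 2723 in replicate 3 and 1688 in the library labelled Tet2 KO replicate 1. In those 5 lists no member other than Vwf passed the threshold, over all genes or adjusted over the list alone. The call of mature B, T and NK cell genes ended with the length and GC trend removed (adjusted p = 0.0919) and with no filter (0.124). Without the library labelled Tet2 KO replicate 1 the calls of the mature neutrophil, macrophage and dendritic cell, lymphoid progenitor and B, T and NK cell lists ended (adjusted p = 0.0678, 0.06, 0.0779 and 0.0678), as they did without Tet2 KO replicate 2 (0.0885, 0.0733, 0.0578 and 0.0733). Those of mature neutrophil and of macrophage and dendritic cell genes also ended without WT replicate 1 (adjusted p = 0.156 and 0.217).

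Growth genes moved little in Tet2 KO. MYC targets had median log2 change 0.14, camera adjusted p = 0.0258, adjusted p = 0.784 with an estimated correlation. Of its 90 members 0 rose and 1 fell, also when adjusted over the list alone: Ung, which encodes the enzyme that removes uracil from DNA and fell from 1678 ± 171 to 145 ± 23.8 (log2 change -3.54 ± 0.30 (SE), adjusted p = 6.96e-05). Ribosome biogenesis genes had median log2 change 0.16, camera adjusted p = 0.017, adjusted p = 0.764 with an estimated correlation. Cytosolic ribosomal protein genes had median log2 change 0.15, camera adjusted p = 0.0489, adjusted p = 0.894 with an estimated correlation. Oxidative phosphorylation genes had median log2 change 0.15, camera adjusted p = 0.0258, adjusted p = 0.894 with an estimated correlation. Over all genes and over each list alone, the called member of those 3 lists was Rpl34, which went the other way than its list (-2.56, adjusted p = 0.033) and shares reads with pseudogenes, so its value is uncertain. With the length and GC trend removed, the MYC target, ribosomal protein and oxidative phosphorylation calls ended (adjusted p = 0.245, 0.836 and 0.992). All 4 calls ended without Tet2 KO replicate 3 (adjusted p = 0.842 for MYC targets, 0.667 for ribosome biogenesis, 0.43 for ribosomal proteins and 0.667 for oxidative phosphorylation). The MYC target and ribosome biogenesis calls also ended without WT replicate 1 (0.156 and 0.0794). Those of ribosomal proteins and oxidative phosphorylation ended without WT replicate 2 (0.0954 and 0.146) or 3 (0.53 and 0.325), and oxidative phosphorylation also without Tet2 KO replicate 2 (0.0658).

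In all, 15 genes rose and 43 fell in Tet2 KO against WT (limma, adjusted), and 1186 had an unadjusted p under 0.05. Groups did not overlap for 19.1% of tested genes, where chance gives 10%. Besides Xist, the largest rises were Eps8l1, an actin regulator (7.68, adjusted p = 0.0089), Akr1e1 (log2 change 6.93 ± 0.47 (SE), adjusted p = 9.43e-06), Rab6b (3.72), Spint1 (3.40), Wdfy1 (664 ± 101 to 4331 ± 611, log2 change 2.71 ± 0.25 (SE), adjusted p = 9.86e-05), Lsm12 (1.86), Sdc1 (1.63) and H2-Ob, which encodes an MHC class II accessory chain (1.52). Besides Thbs1 and Ung, the largest falls were H2-Q1 (-7.31), Gdpd3 (-7.08), H2-Ea-ps (at 0 in Tet2 KO, at least 44.3-fold lower), H2-Q10 (-4.98), H2-Bl (-4.24), Tmem87a (2339 ± 447 to 143 ± 44.6, -4.06), H2-Q2 (-3.90) and H2-Q4 (-3.43). The H2-Q genes are near-identical copies, so their single values are uncertain. Strain was not tested for H2-Ob. Rises and falls numbered 90 and 210 with DESeq2, 68 and 259 with only these 2 groups in the fit and 109 and 427 with the spread weighted by group. They were 10 and 15, 9 and 13, and 9 and 17 without WT replicates 1, 2 and 3, 18 and 128 without the library labelled Tet2 KO replicate 1, and 13 and 21, and 11 and 19, without Tet2 KO replicates 2 and 3.

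The comparison of Traf6 KO with WT asked what Traf6 loss did alone, and its directions include the library labelled Traf6 KO replicate 1, where Traf6 stood at the WT level. Mast cell and basophil genes were higher. Cma1, a mast cell chymase gene, was at 0 in all WT libraries and at 340.4 ± 76.7 (SD, n = 3) in Traf6 KO, at least 121-fold higher (adjusted p = 2.03e-05), and the mast cell tryptase gene Tpsb2 rose from 2.3 ± 4 to 329.5 ± 164 (log2 change 7.21 ± 1.0 (SE), adjusted p = 0.00489). Mcpt8, a basophil protease gene, stood at 142 ± 59.8 in WT and 1315 ± 1317 in Traf6 KO (2.76, adjusted p = 0.111). Of 16 genes of that list 2 rose, 0 fell and 14 passed neither way (8 and 0 adjusted over the list alone). The list had median log2 change 1.54, camera adjusted p = 4.15e-12, and the same median with genes at 0 set to their bound. Its call held with an estimated correlation (adjusted p = 0.00479), but not with an estimated correlation once the length and GC trend was removed (adjusted p = 0.0699, median 1.67). These transcripts were rare next to the list's abundant member Gata2, a stem cell gene too, at 13443 ± 2122 in WT and 13255 ± 1524 in Traf6 KO.

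Interferon response, NF-kB target, early response and stem cell lists were lower in Traf6 KO. The list of Toll-like receptor and TRAF6 signalling itself did not pass (median log2 change -0.14, camera adjusted p = 0.327), and 0 of its 44 members were called. Type I interferon response genes had median log2 change -0.33, camera adjusted p = 0.000827, adjusted p = 0.643 with an estimated correlation. Of 54 members 0 passed over all genes and 3 were lower when adjusted over the list alone, among them Ifi44 (-1.73, adjusted p = 0.226) and Oasl2 (-1.06, adjusted p = 0.235). NF-kB targets had median log2 change -0.24, camera adjusted p = 0.0332, adjusted p = 0.522 with an estimated correlation, with 0 of 40 and, over the list alone, 1 lower: Nfkb2, which encodes an NF-kB subunit (-1.21, adjusted p = 0.133). Relb, its partner subunit, had -1.36, adjusted p = 0.248. Immediate early and dissociation stress genes had median log2 change -0.25, camera adjusted p = 0.0206, adjusted p = 0.643 with an estimated correlation. Of 32 members 1 was called (2 adjusted over the list alone), Hspa1b, a heat shock chaperone gene that fell from 561 ± 185 to 6.3 ± 6.2 (log2 change -6.88 ± 1.21 (SE), adjusted p = 0.0305). Its value is uncertain (near-identical copy Hspa1a), and strain was not tested. Haematopoietic stem cell genes had median log2 change -0.33, camera adjusted p = 0.00311, adjusted p = 0.565 with an estimated correlation, with 1 of 48 lower when adjusted over the list alone, Ltb (-2.14, adjusted p = 0.134). Without Traf6 KO replicate 3 all 4 calls of lower lists ended (adjusted p = 0.0864 for interferon response, 0.0864 for NF-kB targets, 0.101 for early response and 0.0864 for stem cell genes). Those of NF-kB targets and early response genes also ended without the library labelled Traf6 KO replicate 1 (adjusted p = 0.0531 and 0.0816), WT replicate 1 (0.0723 and 0.0713) or WT replicate 2 (0.0743 and 0.0531).

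Of the progenitor, growth and metabolic lists some were higher in Traf6 KO. Ribosome biogenesis (median 0.07, camera adjusted p = 0.169), glycolysis (0.05 and 0.147), G2/M phase (0.08 and 0.069) and lymphoid progenitor genes (0.12 and 0.44) did not pass. Traf6 KO replicate 2 stood apart in this group, at -118.8 on the second principal component, where the library labelled Traf6 KO replicate 1 was at -6.6 and replicate 3 at -18.1. Its slope of -0.361 per doubling of transcript length was the steepest outside dKO, in the direction that raises lists of short transcripts. Neutrophil and monocyte progenitor genes had median log2 change 0.53, camera adjusted p = 5.6e-09, adjusted p = 0.542 with an estimated correlation. Past the threshold were 0 of 39 over all genes and 3 adjusted over the list alone: Ly6c2 (2.93), Elane (3.21) and the Fc receptor gene Fcgr3 (2.08). Oxidative phosphorylation genes had median log2 change 0.41, camera adjusted p = 4.1e-08, adjusted p = 0.744 with an estimated correlation. Ribosomal protein genes had median log2 change 0.28, camera adjusted p = 0.000376, adjusted p = 0.805 with an estimated correlation. G1/S phase genes had median log2 change 0.23, camera adjusted p = 0.000961, adjusted p = 0.565 with an estimated correlation. Unfolded protein response genes had median log2 change 0.23, camera adjusted p = 0.00909, adjusted p = 0.494 with an estimated correlation. Erythroid genes had median log2 change 0.36, camera adjusted p = 0.0425, adjusted p = 0.805 with an estimated correlation. MYC targets had median log2 change 0.15, camera adjusted p = 0.0156, adjusted p = 0.786 with an estimated correlation. In these lists the member past the threshold over all genes was Ung, which fell (log2 change -2.87 ± 0.30 (SE), adjusted p = 0.000347). Apart from the neutrophil genes above, it was also the member called when adjusted over each list alone. The erythroid, ribosomal protein and MYC target calls ended with the length and GC trend removed (adjusted p = 0.153, 0.0674 and 0.0597), and the oxidative phosphorylation median became 0.23. Without Traf6 KO replicate 2 the ribosomal protein, erythroid, MYC target and unfolded protein response calls ended (adjusted p = 0.514, 0.514, 0.45 and 0.0581). The erythroid call also ended without Traf6 KO replicate 3 (0.0864), without WT replicate 2 (0.24) and with no filter (0.0574), and the MYC target call without Traf6 KO replicate 3 (0.124) or WT replicate 1 (0.0996).

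Counts for Traf6 KO against WT were 11 genes higher and 27 lower (limma, adjusted), with 20.7% of tested genes free of overlap between groups against 10% by chance. Other large rises were Akr1e1 (6.57), Pcna-ps2 (3.57), Rab6b (3.38), Sulf2, a heparan sulfatase gene (3.16), Wdfy1 (2.36) and Cyp11a1, which encodes the first enzyme of steroid hormone synthesis (2.15), besides Xist. Pcna-ps2 is a pseudogene of Pcna and may share its reads. Among falls were Gdpd3 (-7.23), H2-Q1 (-6.80), H2-Ea-ps (at least 38-fold lower), H2-Q10 (-4.64), H2-Bl (-4.26), H2-Q2 (-4.23), H2-Q4 (-3.67) and Supt16h, a subunit of the histone chaperone FACT (7964 ± 2133 to 1222 ± 280.2, log2 change -2.69 ± 0.39 (SE), adjusted p = 0.00597). Rises and falls numbered 75 and 92 with DESeq2, 23 and 41 with the length and GC trend removed and 57 and 112 with the spread weighted by group. They were 8 and 11, 8 and 10, and 10 and 10 without WT replicates 1, 2 and 3, and 13 and 27 without the library labelled Traf6 KO replicate 1.

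The lists of genes called against WT in the single knockouts overlapped. In the same direction 25 genes were called in both, 6 higher and 19 lower, where independent lists of these sizes give 0.01 and 0.08. Both comparisons use the same WT libraries. In 20 simulations unchanged groups gave at most 0 shared calls. Those groups were centred on the observed WT means, where a chance shift of the WT libraries cannot show, so the simulations do not decide this. With 3 WT libraries the controls could not be split, so part of the excess may come from them. Of the 25, 23 had coordinates and 8 lay on chromosome 17 between 34 and 37 Mb in the H2 region, the mouse major histocompatibility complex: H2-Ea-ps (34341959 to 34344645), Gm18733, H2-Q1 (35320405 to 35325099), H2-Q2, H2-Q4, H2-Q10, Mdc1 and H2-Bl (36080115 to 36084223). In dKO against WT, 23 of the 25 (92.0%) were called in the same direction, all except Wdfy1 and Xist.

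**Figure D3:**
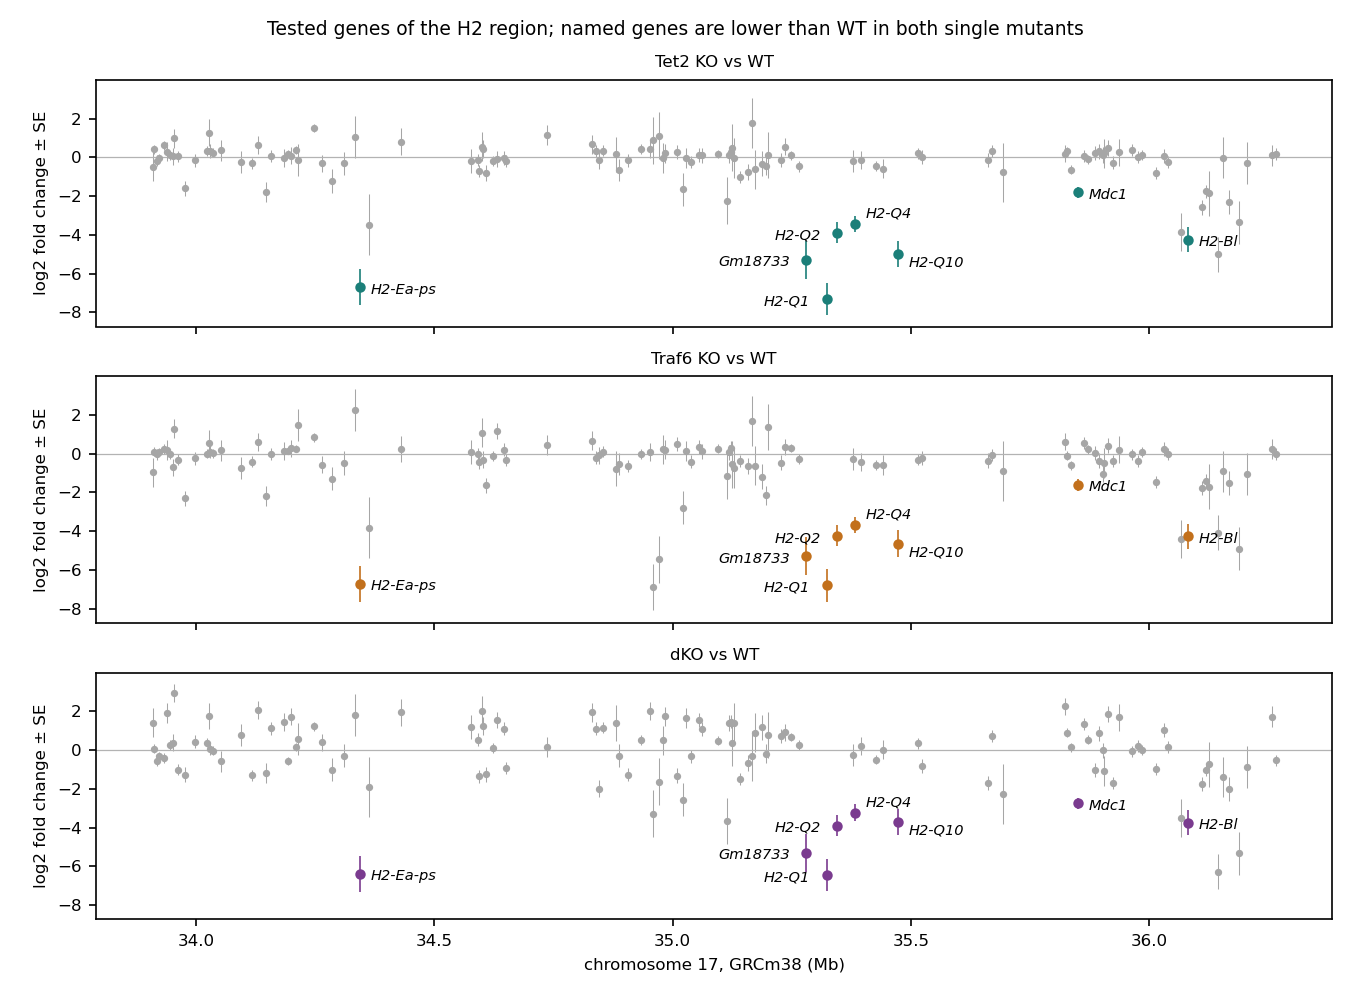
Log2 fold change ± SE against WT (vertical axis) of 127 tested genes along chromosome 17 (horizontal axis, Mb, GRCm38), with 1 panel per mutant genotype. Coloured and named genes were lower than WT in both single knockouts. H2-Q1 was at -7.31, -6.80 and -6.44 in Tet2 KO, Traf6 KO and dKO.

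In dKO against WT, where libraries of both groups carried Y-linked reads, the list of neutrophil and monocyte progenitor genes was higher. Elane went from 264 ± 187 to 12218 ± 7567 (SD, n = 3, log2 change 5.62 ± 0.82 (SE), adjusted p = 0.000463), Prtn3, the proteinase 3 gene, from 2149 ± 484 to 29048 ± 22832 (log2 change 3.51 ± 0.49 (SE), adjusted p = 0.000386), and the monocyte antigen gene Ly6c2 from 22.5 ± 12.5 to 1211 ± 761 (log2 change 5.59 ± 0.70 (SE), adjusted p = 0.000302). Of 39 genes of this list 29 rose, 0 fell and 10 passed neither way (29 and 0 adjusted over the list alone). The list had median log2 change 2.0, camera adjusted p = 3.94e-10, adjusted p = 0.535 with an estimated correlation. With the length and GC trend removed 26 rose and 0 fell at a median of 1.55 (adjusted p = 1.35e-10). Of stem cell and megakaryocyte genes more fell than rose. Mecom, a transcription factor gene needed by stem cells, went from 4383 ± 653 to 638 ± 261 (log2 change -2.85 ± 0.35 (SE), adjusted p = 0.000302), F2r, a thrombin receptor gene, from 11483 ± 1608 to 1889.9 ± 265 (log2 change -2.60 ± 0.23 (SE), adjusted p = 5.64e-05), and Vwf had -4.39, adjusted p = 0.000291.

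Of the 48 stem cell genes 5 rose, 22 fell and 21 passed neither way (5 and 24 adjusted over the list alone). Their list had median log2 change -0.71, camera adjusted p = 0.0142, adjusted p = 0.535 with an estimated correlation. Among 26 megakaryocyte genes 2 rose, 14 fell and 10 passed neither way (2 and 14 adjusted over the list alone). This list had median log2 change -1.06, camera adjusted p = 0.00456, adjusted p = 0.223 with an estimated correlation. These included Zfpm1, the GATA1 partner FOG1 (-2.65), and Mmrn1, a platelet protein gene (-3.42). With the trend removed 17 stem cell and 15 megakaryocyte genes fell, at medians of -0.49 and -1.09 (adjusted p = 0.00798 and 5.78e-06). The stem cell call ended without dKO replicate 1 (adjusted p = 0.116). For erythroid genes, 11 rose and 1 fell (10 and 1 adjusted over the list alone) of 31, with median log2 change 0.91, camera adjusted p = 0.0161, adjusted p = 0.59 with an estimated correlation. Mt2 (4.53) and Car1 (3.77) led it, and the call ended with the trend removed (median 0.68, adjusted p = 0.0982) and without dKO replicate 1 (adjusted p = 0.0569). Of 16 mast cell and basophil genes 10 rose and 2 fell (10 and 2 adjusted over the list alone), with median log2 change 1.99, camera adjusted p = 0.00296, adjusted p = 0.223 with an estimated correlation. After trend removal 6 rose and 1 fell, at a median of 1.14 (adjusted p = 0.0152). Mcpt8 rose to 2789 ± 762 (4.35, adjusted p = 0.000379), while Gata2 fell (-1.63, adjusted p = 0.000413). Lyz2, a macrophage lysozyme gene, stood at 10942, 22434 and 42943 in dKO replicates 1, 2 and 3 and at most 13269 in WT. Igkc, an immunoglobulin gene of B cells, stood at 588, 1673 and 28286.

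Ribosomal protein, oxidative phosphorylation and MYC target lists were higher in the same comparison, beside the length trend of the dKO libraries. Of 81 cytosolic ribosomal protein genes 64 rose and 1 fell (72 and 1 adjusted over the list alone), with median log2 change 1.80, camera adjusted p = 2.59e-15, adjusted p = 0.535 with an estimated correlation. An example was Rplp0 (9728 ± 1445 to 38116 ± 20777, log2 change 1.85 ± 0.34 (SE), adjusted p = 0.00141). Many of these genes share reads with pseudogenes, so single values are uncertain. Of 75 oxidative phosphorylation genes 67 rose and 0 fell (67 and 0 adjusted over the list alone), with median log2 change 1.80, camera adjusted p = 1.05e-16, adjusted p = 0.535 with an estimated correlation. Among them was Ndufa10 of complex I (1.70). Their median longest transcripts were 1059 and 1231 nucleotides against 3204.5 over all genes. With the trend removed their medians were 0.38 and 0.36, with 24 and 22 genes higher (adjusted p = 0.000227 and 4.12e-06). Among 90 MYC targets 43 rose, 9 fell and 38 passed neither way (46 and 10 adjusted over the list alone). MYC targets had median log2 change 0.59, camera adjusted p = 0.000215, adjusted p = 0.535 with an estimated correlation. Gnl3, the nucleostemin gene, rose (log2 change 1.33 ± 0.21 (SE), adjusted p = 0.000634), while Ung (-2.69), Cad, which encodes the first enzyme of pyrimidine synthesis (-2.79), and Utp20 (-3.15) fell. With the trend removed 25 MYC targets rose and 6 fell, at a median of 0.25 (adjusted p = 0.00229). Ribosome biogenesis genes had median log2 change 0.58, camera adjusted p = 0.00641, adjusted p = 0.535 with an estimated correlation, and 37 rose and 17 fell (40 and 17 adjusted over the list alone) of 78. After trend removal 27 of them rose and 8 fell, at a median of 0.20 (adjusted p = 0.00392), and the call as deposited ended without dKO replicate 1 (adjusted p = 0.0857).

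Of early response genes more rose than fell in dKO against WT, and of lipid synthesis genes more fell than rose. Of 32 immediate early and dissociation stress genes 17 rose and 3 fell (18 and 3 adjusted over the list alone), with median log2 change 1.07, camera adjusted p = 0.000857, adjusted p = 0.535 with an estimated correlation. They included Junb (2076 ± 227 to 9521 ± 2258, 2.18, adjusted p = 0.00053) and Fosb (3.48), both subunits of AP-1. Trend removal left 15 that rose and 0 that fell, at a median of 0.91 (adjusted p = 0.000227). For cholesterol and fatty acid synthesis, 2 rose and 14 fell (2 and 14 adjusted over the list alone) of 30, with median log2 change -0.68, camera adjusted p = 0.0242, adjusted p = 0.535 with an estimated correlation. Among those that fell was Fasn, the fatty acid synthase (5924 ± 1904 to 733 ± 205, -2.99, adjusted p = 0.000349). DNA methylation and TET partner genes had median log2 change -1.26, camera adjusted p = 0.0358, adjusted p = 0.535 with an estimated correlation, and 2 rose and 11 fell (2 and 11 adjusted over the list alone) of 16, including Dnmt1, the maintenance methyltransferase (-2.09). Those last 2 lists were no longer past the threshold with the trend removed (adjusted p = 0.494 and 0.807, medians -0.23 and 0.08), with 4 lipid synthesis genes higher and 8 lower, and the DNA methylation list also ended without dKO replicate 3 (adjusted p = 0.0745).

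**Figure D4:**
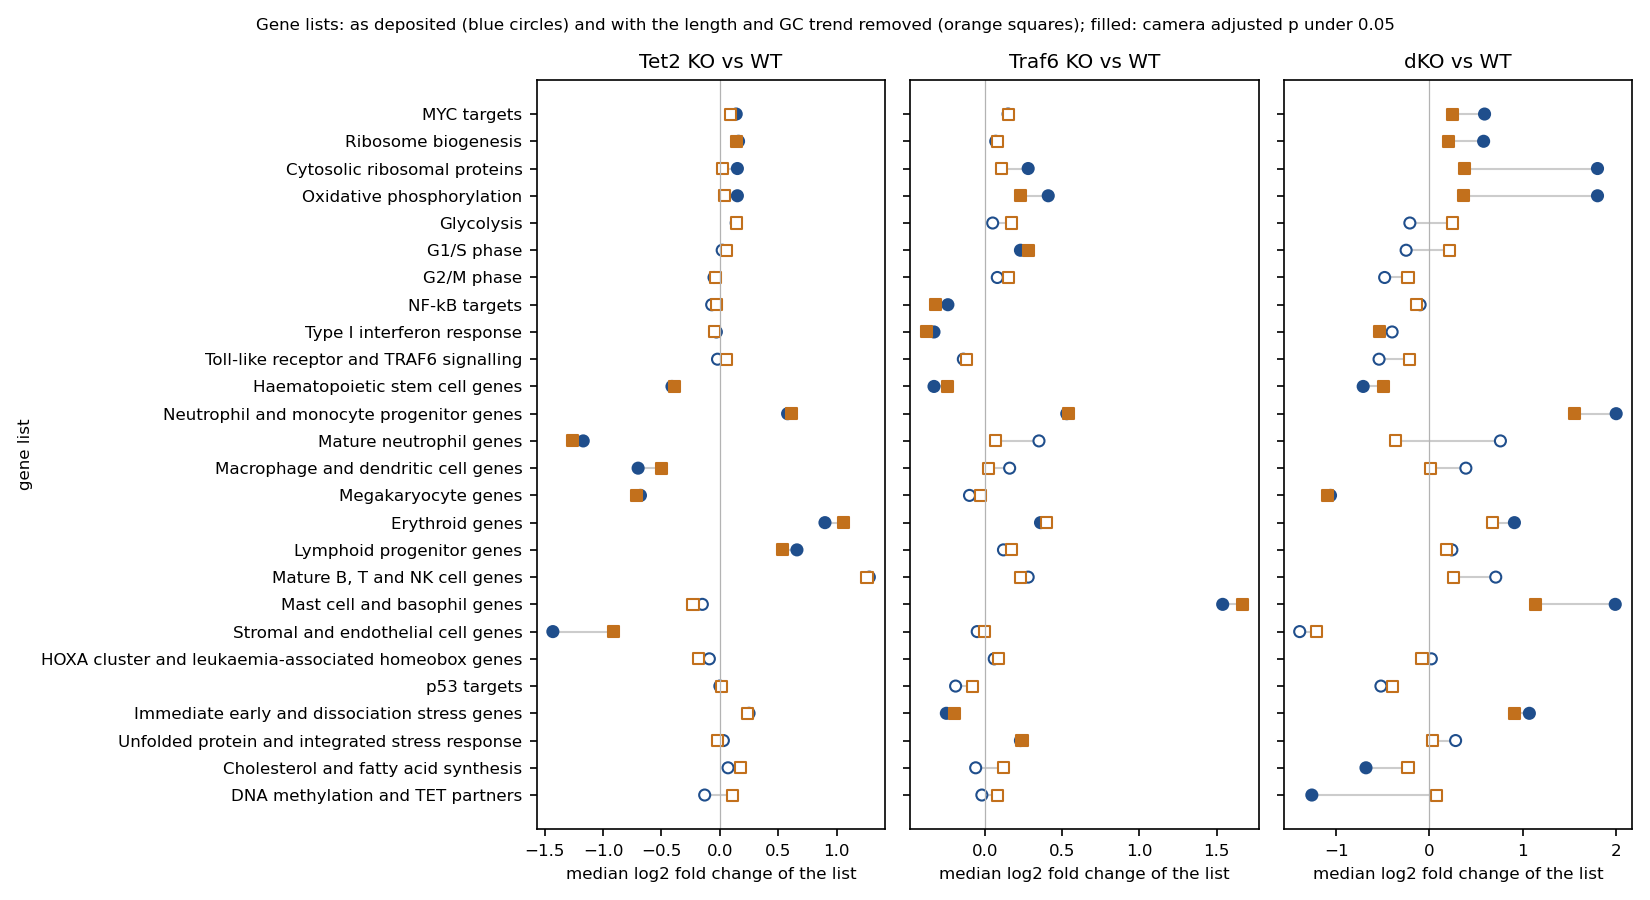
Median log2 fold change of the 26 gene lists (horizontal axis) in Tet2 KO, Traf6 KO and dKO against WT, 1 panel each, as deposited (circles) and with the length and GC trend removed (squares), where filled symbols have a camera adjusted p under 0.05 at the preset correlation. In dKO the ribosomal protein and oxidative phosphorylation medians move from 1.80 to 0.38 and from 1.80 to 0.36, while megakaryocyte genes stay at -1.06 and -1.09.

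Over all genes, 3074 rose and 3716 fell in dKO against WT (limma, adjusted), and 58.4% of tested genes had no overlap between groups, against 10% by chance. Other large rises were Akr1e1 (7.58), Pcna-ps2 (5.84), Cd14, the lipopolysaccharide co-receptor gene (8.5 ± 4.4 to 473 ± 91.8, 5.77), Hp (5.32), Tpsb2 (5.28) and, from 0 in every WT library, Cma1, Sfrp4 and Cd200r3 (at least 34-, 28.1- and 22.8-fold). Other large falls were H2-Q1, H2-Ea-ps, Gdpd3, Evc2 (-6.37), Mpdz (-6.29), Arhgef16 (-6.18), Clip4 (-5.93), Thsd4 (-5.89), Myo1e (-5.82) and Robo1, at 0 in every dKO library (at least 14.7-fold lower). With equal library totals 2291 genes rose and 4166 fell and the median of all genes moved from -0.09 to -0.34, so directions of small changes are relative to that scaling. Without WT replicate 2, 1957 rose and 2750 fell, and 1969 and 2785 without WT replicate 3. With the length and GC trend removed 2172 rose and 1823 fell, and 2031 and 1541 without dKO replicate 3 as well.

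The comparison of dKO with Tet2 KO asked what Traf6 loss did where Tet2 was also lost, and set libraries with Y-linked reads against libraries without. Traf6 itself did not pass there (log2 change -0.99 ± 0.46 (SE), adjusted p = 0.108), while Tet2 did (log2 change -0.99 ± 0.35 (SE), adjusted p = 0.0432) as deposited but not with the length and GC trend removed (0.11). Its directions include the library labelled Tet2 KO replicate 1. The mast cell list was higher. Mcpt8 went from 142 ± 20 to 2789 ± 762 (SD, n = 3, log2 change 4.26 ± 0.60 (SE), adjusted p = 0.00349) and Fcer1a, which encodes the IgE receptor alpha chain, from 23.7 ± 12 to 581 ± 354 (log2 change 4.49 ± 0.63 (SE), adjusted p = 0.00342). Cma1, Tpsb2 and Cd200r3 were at 0 in all Tet2 KO libraries (at least 37.7-, 44- and 25.2-fold). Of the 16 genes of that list 9 rose and 1 fell (9 and 1 adjusted over the list alone), with median log2 change 2.12, camera adjusted p = 0.000154, adjusted p = 0.15 with an estimated correlation. The median was 2.37 with genes at 0 set to their bound. Among neutrophil granule genes Ctsg, the cathepsin G gene, went from 2473 ± 1226 to 29201 ± 17935 (log2 change 3.50 ± 0.66 (SE), adjusted p = 0.00704), and Prtn3 had 2.51, adjusted p = 0.00737. For the progenitor list 20 rose and 1 fell (23 and 1 adjusted over the list alone) of 39, with median log2 change 1.58, camera adjusted p = 4.04e-07, adjusted p = 0.61 with an estimated correlation. Mature neutrophil genes had median log2 change 2.21, camera adjusted p = 0.000738, adjusted p = 0.61 with an estimated correlation, and 10 rose and 2 fell (10 and 2 adjusted over the list alone) of 20, with S100a9 at 85.8 in Tet2 KO and 1091 in dKO (3.10, adjusted p = 0.00945). With the length and GC trend removed 7, 13 and 4 genes of these 3 lists rose, at lower medians of 1.25, 0.85 and 1.03 (adjusted p = 0.000207, 8.09e-07 and 0.0139).

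Growth lists were higher in dKO than in Tet2 KO. Among 90 MYC targets 32 rose, 9 fell and 49 passed neither way (35 and 10 adjusted over the list alone). As a list they had median log2 change 0.46, camera adjusted p = 0.000393, adjusted p = 0.61 with an estimated correlation. Npm1, the nucleophosmin gene, rose (log2 change 1.22 ± 0.26 (SE), adjusted p = 0.00914), as did Ldha, lactate dehydrogenase (1.17, adjusted p = 0.00613), while Ipo4 (-1.46) and Polr1b, an RNA polymerase I subunit gene (-1.69), fell. Ribosome biogenesis genes had median log2 change 0.34, camera adjusted p = 0.0336, adjusted p = 0.745 with an estimated correlation, and 27 rose and 12 fell (29 and 14 adjusted over the list alone) of 78. After trend removal 19 of them rose and 3 fell, at a median of 0.09 (adjusted p = 0.0233). The ribosome biogenesis call as deposited ended with equal library totals (adjusted p = 0.0776), without the library labelled Tet2 KO replicate 1 (0.121), without Tet2 KO replicate 2 (0.0603) and without dKO replicate 1 (0.368). Of 81 ribosomal protein genes 58 rose and 1 fell (60 and 1 adjusted over the list alone), with median log2 change 1.67, camera adjusted p = 8.23e-18, adjusted p = 0.61 with an estimated correlation. Of 75 oxidative phosphorylation genes 66 rose and 0 fell (66 and 0 adjusted over the list alone), with median log2 change 1.69, camera adjusted p = 4.64e-19, adjusted p = 0.61 with an estimated correlation. Beside the length trend of the dKO libraries, the medians with that trend removed were 0.19 for MYC targets, 0.42 for ribosomal proteins and 0.32 for oxidative phosphorylation (adjusted p = 0.0021, 5.07e-06 and 7.88e-08), with 18, 17 and 17 genes higher. Myc itself had log2 change 0.20 ± 0.24 (SE), adjusted p = 0.529, or -0.05 with equal library totals. Of 32 early response genes 13 rose and 2 fell (13 and 2 adjusted over the list alone), with median log2 change 0.87, camera adjusted p = 0.000564, adjusted p = 0.61 with an estimated correlation. These included Fosb (3.39), Egr1 (2.48) and Klf2 (2.79). Trend removal left 7 early response genes that rose and 1 that fell, at a median of 0.63 (adjusted p = 8.49e-05). For cholesterol and fatty acid synthesis 0 rose and 13 fell (0 and 15 adjusted over the list alone) of 30, with median log2 change -0.76, camera adjusted p = 0.0039, adjusted p = 0.61 with an estimated correlation. Scd2 (-2.37) and Srebf1, a regulator of lipid synthesis (-1.71), fell. The call of the list ended with the trend removed (median -0.45, adjusted p = 0.171).

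In total 2174 genes rose and 2789 fell in dKO against Tet2 KO (limma, adjusted), and 46.2% of tested genes had no overlap between groups against 10% by chance. The largest changes included the Y-linked Eif2s3y (9.49), Ddx3y (7.39), Kdm5d (6.90) and Uty (6.46), and Xist (-9.90). Gzmb, the granzyme B gene (7.59, adjusted p = 0.00503), Pcna-ps2 (6.25, adjusted p = 1.85e-05) and Rcvrn (at 0 in Tet2 KO, at least 24.4-fold) also rose, and Nrk (-5.64), Fbxo40 (-5.37), Ccr9, a chemokine receptor gene (-5.15), Eif3j (-5.06), Myo1e (-4.76), Rapgefl1 (-4.73), Apob (-4.64) and Cap2 (-4.53) fell. With only these 2 groups in the fit 16 genes rose and 8 fell, with the length and GC trend removed 1244 rose and 993 fell, without dKO replicate 3 as well 901 and 631, and with the spread weighted by group 1260 and 1799. With equal library totals 1458 rose and 3437 fell at a median of -0.36 over all genes (-0.12 as deposited), and 206 rose and 661 fell without the library labelled Tet2 KO replicate 1. Rises and falls were 1340 and 2090 without Tet2 KO replicate 2, and 1570 and 1733 without dKO replicate 2, and 1214 and 2076 without dKO replicate 3.

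The last pairwise comparison, dKO against Traf6 KO, asked what Tet2 loss did where Traf6 was lost or labelled as lost, and its directions include the library labelled Traf6 KO replicate 1. Neither Tet2 (log2 change -0.88 ± 0.35 (SE), adjusted p = 0.0619) nor Traf6 (log2 change -0.08 ± 0.46 (SE), adjusted p = 0.903) passed, and trend removal turned both above 0 without a call (0.49 and 0.90, adjusted p = 0.146 and 0.164). Traf6 was also above 0 without the library labelled Traf6 KO replicate 1 (0.53) and without dKO replicate 1 (0.08). The early response list was higher. Fos went from 1049.5 ± 759.8 to 24172 ± 8878 (SD, n = 3, log2 change 4.68 ± 0.71 (SE), adjusted p = 0.00199), and Junb had 2.18, adjusted p = 0.00199. Of 32 genes of this list 21 rose and 0 fell (21 and 0 adjusted over the list alone), with median log2 change 1.5, camera adjusted p = 1.9e-07, adjusted p = 0.259 with an estimated correlation. The megakaryocyte list was lower, with F2r going from 8265 ± 1858 to 1889.9 ± 265 (log2 change -2.11 ± 0.23 (SE), adjusted p = 0.000592) and Zfpm1 at -2.44. Of 26 members 1 rose and 11 fell (1 and 12 adjusted over the list alone), with median log2 change -0.98, camera adjusted p = 0.000556, adjusted p = 0.154 with an estimated correlation. For neutrophil and monocyte progenitor genes 23 rose and 0 fell (25 and 0 adjusted over the list alone) of 39, with median log2 change 1.49, camera adjusted p = 7.49e-07, adjusted p = 0.716 with an estimated correlation. Among them were Prtn3 (2.43) and Sfpi1, which encodes the myeloid factor PU.1 (1.44). These 3 calls held with the length and GC trend removed at the preset correlation (medians 1.28, -1.09 and 1.02, adjusted p = 9.63e-09, 1.23e-07 and 3.01e-06), with 16 early response and 12 progenitor genes higher and 11 megakaryocyte genes lower.

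Growth lists were higher in dKO than in Traf6 KO too. For MYC targets 38 rose and 10 fell (40 and 10 adjusted over the list alone) of 90, with median log2 change 0.46, camera adjusted p = 0.00141, adjusted p = 0.727 with an estimated correlation. With the trend removed 17 rose and 5 fell (median 0.17, adjusted p = 0.0275). Gnl3 rose (1.11, adjusted p = 0.00318) and Cad fell (-2.62, adjusted p = 0.00208). Ribosome biogenesis genes had median log2 change 0.46, camera adjusted p = 0.0162, adjusted p = 0.727 with an estimated correlation, and 33 rose and 12 fell (35 and 12 adjusted over the list alone) of 78. After trend removal 22 of them rose and 4 fell, at a median of 0.20 (adjusted p = 0.0109), and the call as deposited ended without the library labelled Traf6 KO replicate 1 (adjusted p = 0.172) or dKO replicate 1 (0.227). Of the ribosomal protein genes 60 rose and 0 fell (67 and 2 adjusted over the list alone) of 81, with median log2 change 1.55, camera adjusted p = 9.54e-14, adjusted p = 0.716 with an estimated correlation. Of oxidative phosphorylation genes 63 rose and 0 fell (67 and 0 adjusted over the list alone) of 75, with median log2 change 1.38, camera adjusted p = 1.37e-13, adjusted p = 0.716 with an estimated correlation, beside the length trend of the dKO libraries. With that trend removed the medians were 0.36 and 0.15 (adjusted p = 0.00329 and 0.0205). Then 11 ribosomal protein genes rose and 2 fell, 4 oxidative phosphorylation genes rose, and the call of the latter list ended without dKO replicate 3 as well (adjusted p = 0.139). For cholesterol and fatty acid synthesis 0 rose and 12 fell (0 and 12 adjusted over the list alone) of 30, with median log2 change -0.84, camera adjusted p = 0.00264, adjusted p = 0.716 with an estimated correlation. For DNA methylation and TET partners 2 rose and 8 fell (2 and 9 adjusted over the list alone) of 16, with median log2 change -0.86, camera adjusted p = 0.0254, adjusted p = 0.716 with an estimated correlation. The latter included the X-linked demethylase gene Kdm6a, which escapes X inactivation (-2.96, adjusted p = 0.000592), and neither list was past the threshold with the trend removed (adjusted p = 0.127 and 0.819, medians -0.32 and -0.22).

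Here 2432 genes rose and 2910 fell (limma, adjusted), and 45.0% of tested genes had no overlap between groups against 10% by chance. Besides Eif2s3y (7.89) and Xist (-9.89), large rises were Igll1, a surrogate light chain gene of pro-B cells (5.61), Cd14 (5.46), Hist4h4 (4.86) and Hist2h4 (4.41), which are copies of histone H4 and uncertain, Dpep2 (4.78), Tmem51 (4.66), Ephx2 (4.63) and Klrd1, an NK cell receptor gene (4.17). Large falls were Gpr64 (-5.68), Agphd1 (-5.30), Abat (-5.24), Evc2 (-5.22), Mpdz (-5.13), Dsg2 (-5.00), L1cam (-4.96), Evc (-4.93) and Myo1e (-4.86). The balance of rises and falls moved with the setting. With only these 2 groups in the fit 78 rose and 892 fell, with the spread weighted by group 941 and 1941, with no filter 1504 and 2393, and with equal library totals 1773 and 3119. The length and GC trend removed, 1480 rose and 1256 fell, or 1025 and 874 without dKO replicate 3 as well. As deposited, 508 rose and 1766 fell without the library labelled Traf6 KO replicate 1, 432 and 1637 without Traf6 KO replicate 3, and 836 and 2254 without dKO replicate 3.

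The interaction asked whether Traf6 loss had another effect where Tet2 was lost, and its directions include the libraries labelled Tet2 KO replicate 1 and Traf6 KO replicate 1. It called 15 genes above 0 and 16 below (limma, adjusted), among them Wdfy1, at 664 ± 101 in WT, 4331 ± 611 in Tet2 KO, 3468 ± 892 in Traf6 KO and 416 ± 49.7 in dKO (log2 change -5.74 ± 0.35 (SE), adjusted p = 4.13e-06), and Tmem87a, low in Tet2 KO (143 ± 44.6) and at 3485 ± 1527 in dKO (log2 change 4.65 ± 0.53 (SE), adjusted p = 0.00109). Wdfy1 was arranged like the sex-linked reads, so sex cannot be told apart there. For Tmem87a a strain difference was not tested. Myc had log2 change 0.46 ± 0.34 (SE), adjusted p = 0.411, and 0.29 with the length and GC trend removed. Leave-outs gave Myc 0.21 (without the library labelled Traf6 KO replicate 1) to 0.65 (without Traf6 KO replicate 3). Across the 14045 genes, which are not independent replicates, the log2 changes of dKO against Tet2 KO and of Traf6 KO against WT, which share no library, were correlated with Pearson r = 0.309 and Spearman rho = 0.424. Calls shared in direction numbered 4 upward, where independent lists give 1.7, and 5 downward, where they give 5.36. Once the length and GC trend was removed they numbered 12 upward against 2.09 and 7 downward against 2.98, while the correlations were 0.251 and 0.313. Genes above and below 0 numbered 95 and 164 with DESeq2, and 14 and 28 with the trend removed and without dKO replicate 3. They were 5 and 10, 5 and 9, and 7 and 10 without WT replicates 1, 2 and 3, 12 and 10 without the library labelled Tet2 KO replicate 1, 10 and 10 without Traf6 KO replicate 3, and 720 and 1725 without dKO replicate 1. Without Traf6 KO replicate 2 the Pearson correlation was 0.173.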

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

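The removal of the length and GC trend and the tests of explanations in the last 3 paragraphs of this part were chosen after the results were seen, while the interaction tests and the splits of the libraries were fixed before. The 31 genes called for the interaction, with 15 above 0 and 16 below, and 8 gene lists were singled out because the test of the difference between both Traf6 effects passed. Above 0 were Eif2s3y (16.65 on the log2 scale), Gdpd3 (8.51), H2-Q1 (7.67), H2-Q10 (5.90), Tmem87a (4.65), H2-Q2 (4.23), H2-Q4 (3.88), Ung (3.71) and Gimap4 (2.88). For Gdpd3, Ung and the H2-Q genes the value came from WT, far above all 3 mutant genotypes, with Ung at 1678, 145, 229.8 and 266 in WT, Tet2 KO, Traf6 KO and dKO. Below 0 were Xist (-18.55), Eps8l1 (-9.93), Rapgefl1 (-6.77), Akr1e1 (-5.92), Wdfy1 (-5.74), Eif3j (-5.45), Fam169a (-5.02), Rab6b (-4.88), Kcnip3 (-3.78) and Unc5a (-3.36). For Akr1e1 and Rab6b WT also stood apart, below all 3 mutants. Xist and Eif2s3y followed the sex-linked reads, themselves arranged like an interaction.

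Among lists, medians of the interaction were 0.24 for MYC targets (camera adjusted p = 0.0144, 0.919 with an estimated correlation), 1.38 for ribosomal proteins (5.43e-14 and 0.858), 1.24 for oxidative phosphorylation (6.14e-13 and 0.858), 0.60 for neutrophil and monocyte progenitor genes (0.0192 and 0.919), 1.59 for mature neutrophil genes (0.0112 and 0.858), 1.43 for macrophage and dendritic cell genes (0.0192 and 0.889), 1.25 for immediate early genes (7.76e-08 and 0.458) and -0.76 for cholesterol and fatty acid synthesis (0.000409 and 0.858). Of their members Ung, a MYC target, was past the threshold over all genes, and none in the other 7 lists. Adjusted over the list alone 9 immediate early genes were higher and 6 lipid genes lower, and in the macrophage and dendritic cell list 1 was higher and 1 lower. Once the length and GC trend was removed, the calls of MYC targets, neutrophil and monocyte progenitor and mature neutrophil genes ended (medians 0.13, 0.23 and 0.80, adjusted p = 0.102, 0.13 and 0.14). The medians became 0.30 for ribosomal proteins (adjusted p = 0.00228), 0.15 for oxidative phosphorylation (0.0271), 1.01 for macrophage and dendritic cell genes (0.041), 0.93 for immediate early genes (6.01e-09) and -0.45 for lipid synthesis (0.0271), and erythroid genes passed at -0.74 (0.0278). Without dKO replicate 3 as well, the oxidative phosphorylation and macrophage and dendritic cell calls ended (adjusted p = 0.142 and 0.429). As deposited, the MYC target and progenitor calls ended without the library labelled Traf6 KO replicate 1 (adjusted p = 0.227 and 0.546), the library labelled Tet2 KO replicate 1 (0.118 and 0.116), WT replicate 3 (0.054 and 0.102) or dKO replicate 1 (0.115 and 0.0699). The mature neutrophil call ended without the library labelled Traf6 KO replicate 1 (0.0593) or dKO replicate 2 (0.0513), and that of macrophage and dendritic cell genes with no filter (0.0645) and without Tet2 KO replicate 2 (0.0553), Traf6 KO replicate 2 (0.0868) or dKO replicate 3 (0.0897).

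The groups of each pairwise comparison could be split in 10 ways, too few for a share under 0.05. The real splits called 58, 38, 6790, 4963 and 5342 genes, 1 split of 10 in each comparison called as many, and the highest of the other splits called 0, 0, 0, 0 and 2. Of 100 groupings drawn for the interaction, 2 called at least the real 31, the real one included. The other called 3384, many times the real count, which points to a structure of the samples. It kept the dKO libraries together, as did another grouping that called 0, and the structure itself was not tested. The groupings shuffled all 12 libraries, and mixing genotypes widens the spread within groups. The share of 2 in 100 thus tests for differences of any kind and cannot exclude chance for the interaction.

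Ribosomal protein genes were higher in dKO than in Tet2 KO (median 1.67), as were oxidative phosphorylation genes (1.69) and MYC targets (0.46). Against the length trend as the whole cause, 10000 random lists matched on transcript length and mean signal had medians of 1.19, 1.20 and 0.19, with upper limits of 1.35, 1.33 and 0.38, although random lists are less co-expressed than real ones. Against sex, the ribosomal median was 1.80 between dKO and WT, whose sex-linked reads were alike. The authors' scaling moves all genes of a library alike and does not account for the list's excess over all genes, 1.07 to 3.04 in dKO libraries and -0.12 to 0.36 in Tet2 KO (means 1.75 apart), while the rise itself, 1.41 with equal library totals, depends on the scaling chosen. Much of the ribosomal and oxidative phosphorylation rise went with transcript length, as the list medians were 0.42 and 0.32 with the trend removed. The matched medians do not measure that share, since genes of the other lists could be drawn and raise them. No list was past the threshold with an estimated correlation (0.61 for each of these 3). A loss of Traf6 together with Tet2, RNA quality and a change in the mix of cells may each account for the rest.

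Of the 25 genes called against WT in both single knockouts, 8 of the 23 with coordinates had another of them within 1 Mb, all in the H2 region, against a median of 0 and an upper limit of 4 in 10000 random sets. Sex does not account for most of the set, since 92.0% were also called in the same direction between dKO and WT. Of all tested genes 48.3% were called there. The exceptions, Xist and Wdfy1, had -1.24 and -0.67 in dKO against WT and were arranged like the sex-linked reads. Chance values of the shared WT libraries stay open, as the 20 simulations (at most 0 shared calls) cannot show them. A strain difference around the H2 region between the WT mice and all 3 mutant groups is a candidate explanation for those 8 genes. For the others, such as Ung and Akr1e1, a strain difference elsewhere or an effect common to the mutants stays open. Strain was not tested for genes outside the 25, such as Thbs1.

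The library labelled Traf6 KO replicate 1 held Traf6 at 2474 and Y-linked reads. RNA of these WT mice would bring all WT transcripts. Yet here 12 genes nearly absent from Tet2 KO and dKO but not WT stood at 1.5% of the WT mean (median, 0 to 18.3%). For 4 Y-linked genes it was 47.8% (40.2 to 73.6%). A male library under a wrong label is argued against by Xist at 1574, where WT and dKO reached 17. Pooled animals of both sexes could give the 47.8%. Xist alone does not fix the female share and no label tells of pooling, so other mixtures stay open. Incomplete Traf6 deletion and Traf6-intact cells of mutant strain, which may lack the 12 genes, were not tested.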

How the results depend on the processing

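The alternatives with the length and GC trend removed and with the spread weighted by group were chosen after the data were seen, as were the leave-outs of the Traf6 effect correlation and, for Tet2, Traf6 and Myc, all alternatives but another pseudocount and equal totals, the others before. For each comparison the cause of a changed count was not tested unless fewer samples or another spread explain it. Counts of called genes in Tet2 KO against WT (58) became 536 weighted, 327 with 2 groups alone and 300 with DESeq2. Traf6 KO against WT (38) gave 64 with the trend removed, 169 weighted and 167 with DESeq2. Trend removal, the same without dKO replicate 3, and the same with the replicate block gave 3995, 3572 and 3891 for dKO against WT (6790), 2237, 1532 and 2139 for dKO against Tet2 KO (4963) and 2736, 1899 and 2593 for dKO against Traf6 KO (5342). The latter 2 gave 3059 and 2882 weighted, and 24 and 970 with 2 groups alone. The interaction (31) gave 259 with DESeq2. Leaving out 1 library gave 22 to 146, 18 to 40, 4707 to 7768, 867 to 6724, 2069 to 6946 and 14 to 2445 genes in the 6 comparisons. Lists past the threshold numbered 13, 12, 12, 9, 9 and 8, or 1, 1, 0, 0, 0 and 0 with an estimated correlation and 1, 0, 0, 0, 0 and 0 with the trend removed as well. The interaction had 5 lists with the trend removed and without dKO replicate 3. Leave-outs gave 8 (without Tet2 KO replicate 2) to 12 lists in Tet2 KO, 6 (without Traf6 KO replicate 3) to 14 in Traf6 KO and 5 (without the library labelled Traf6 KO replicate 1) to 10 in the interaction. The Pearson correlation of the Traf6 effects (0.309) was 0.371 over genes with a mean of at least 100, 0.251 with the trend removed, and 0.173 (without Traf6 KO replicate 2) to 0.358 in leave-outs. For Tet2, removing the trend alone, without dKO replicate 3, and with the replicate block turned -1.39 in dKO against WT to 0.31, 0.24 and 0.31, and -0.99 in dKO against Tet2 KO to 0.11, 0.06 and 0.11. The last -0.99 also missed the threshold without a filter, weighted and with 2 groups alone (-0.99 in each), and without the library labelled Tet2 KO replicate 1 (-0.79), Tet2 KO replicates 2 and 3 (-1.15 and -1.02) and dKO replicates 2 and 3 (-0.80 and -1.0), and reached -1.16 (without dKO replicate 1). Traf6 in dKO against WT (-1.36) became -0.18, -0.22 and -0.18, and missed the threshold weighted (-1.36) and without WT replicates 2 and 3 (-1.25 and -1.26) and dKO replicates 1 and 3 (-1.19 and -1.33), and reached -1.57 (without WT replicate 1). In dKO against Traf6 KO, Tet2 (-0.88) passed with equal totals (-1.07), edgeR (-0.98), DESeq2 (-0.91) and without Traf6 KO replicate 2 (-1.12) or dKO replicate 1 (-1.05), turned to 0.49, 0.43 and 0.49 in the 3 fits with the trend removed, and was -0.57 without the library labelled Traf6 KO replicate 1. Myc there (0.63) passed with DESeq2 (0.62) and without Traf6 KO replicate 3 (0.82) or dKO replicate 3 (0.80), and was 0.38 without the library labelled Traf6 KO replicate 1. Trend removal also turned Tet2 in Tet2 KO (-0.41 to 0.19) and in the interaction (-0.47 to 0.30) and Traf6 in dKO against Traf6 KO (-0.08 to 0.90). Traf6 in the interaction (0.29) was -0.16 without Traf6 KO replicate 3, -0.10 with edgeR and -0.01 with DESeq2. Of 689 other pairs of gene and comparison taken by the naming rule (393 called), 8 called and 2 uncalled pairs changed sign, each with the trend removed, Asxl1 in dKO against Traf6 KO to 0.01 (without dKO replicate 3) among them. Of named gene values 302 kept their side of the threshold, 6 gained a call and 35 lost it with the trend removed, 213, 16 and 64 with 2 groups alone, and 2138, 37 and 183 over all leave-outs. With the trend removed, 7 of 9 and 7 of 10 genes named above and below 0 in the interaction stayed called. The replicate numbers did not pair the libraries: 2 of 15 same-numbered pairs correlated above 0.1 and 4 of 12 libraries correlated best with their own number. With the replicate block, 45, 29, 6574, 4633, 4917 and 25 genes were called, and adjusted p went from 0.0332 to 0.0512 for NF-kB targets in Traf6 KO and from 0.0549 to 0.0381 for early response genes in Tet2 KO. Depth limits genes near the floor, and 3 libraries per group limit the rest.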

Other observations

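The tests of gene lists in this part were fixed before the data were examined, while the removal of the length and GC trend was chosen after. Some signalling genes changed in dKO against WT within lists that were not past the camera threshold as a whole. Of 54 type I interferon response genes 10 rose and 18 fell (10 and 18 adjusted over the list alone), with median log2 change -0.40, camera adjusted p = 0.357. They included the interferon signal transducer Stat2 (1882 ± 142 to 330.0 ± 137, SD, n = 3, log2 change -2.58 ± 0.29 (SE), adjusted p = 0.000291), the antiviral enzyme Oas3 (-3.41) and the RNA sensor Ddx58 (-1.88). For NF-kB targets 9 rose and 12 fell (11 and 12 adjusted over the list alone) of 40, with median log2 change -0.10, camera adjusted p = 0.958. The NF-kB inhibitor gene Tnfaip3 (-3.11, adjusted p = 0.000311) and Nfkb2 (-1.59, adjusted p = 0.00107) fell, while the chemokine gene Ccl3 rose (3.05, adjusted p = 0.00148). Toll-like receptor and TRAF6 signalling had median log2 change -0.54, camera adjusted p = 0.0916, and 3 rose and 17 fell (3 and 16 adjusted over the list alone) of 44, with Traf3 (-2.73), Cyld (-2.07) and Tab3 (-2.43) lower and Cd14 higher. With the length and GC trend removed 5 interferon genes rose and 16 fell (median -0.53, camera adjusted p = 0.0152, adjusted p = 0.776 with an estimated correlation, 0.881 as deposited). The NF-kB and Toll-like receptor medians were then -0.14 and -0.21 (adjusted p = 0.979 and 0.221).

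Cell cycle, p53, glycolysis and HOXA genes went both ways in dKO against WT as deposited. Of 31 p53 targets 2 rose and 9 fell (2 and 7 adjusted over the list alone), with median log2 change -0.52, camera adjusted p = 0.357. Cdkn1a, which encodes the cell cycle inhibitor p21, rose (log2 change 2.88 ± 0.50 (SE), adjusted p = 0.00103), while Trp53inp1 (-2.04), Apaf1 (-2.40) and Sesn2 (-2.05) fell. G1/S phase genes had median log2 change -0.25, camera adjusted p = 0.65, and 13 rose and 12 fell (14 and 13 adjusted over the list alone) of 44, while trend removal left 12 that rose and 2 that fell (median 0.21, adjusted p = 0.221). G2/M phase genes had median log2 change -0.48, camera adjusted p = 0.422, and 11 rose and 15 fell (11 and 16 adjusted over the list alone) of 53. Glycolysis genes had median log2 change -0.21, camera adjusted p = 0.374, with a mean of 0.09 of the other sign, and 7 rose and 3 fell (7 and 3 adjusted over the list alone) of 26. The HOXA cluster and leukaemia-associated homeobox genes had median log2 change 0.02, camera adjusted p = 0.958, with a mean of -0.04 of the other sign, and 1 rose and 3 fell (1 and 3 adjusted over the list alone) of 15. With the trend removed the medians were -0.40 for p53 targets, -0.23 for G2/M phase, 0.25 for glycolysis and -0.08 for HOXA genes (adjusted p = 0.359, 0.636, 0.0614 and 0.636). Supt16h, which fell in Traf6 KO, did not pass the test in Tet2 KO against WT (0.86, adjusted p = 0.557), and stood at 7964 ± 2133 in WT, 14156 ± 1527 in Tet2 KO, 1222 ± 280.2 in Traf6 KO and 3418 ± 2398 in dKO.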
